A study of Mus musculus with 12 samples.

How the data were processed

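The series measured RNA by Smart-Seq2, a full-length cDNA amplification method for very small amounts of RNA, in bone marrow progenitors of C57BL/6 mice that, per the series title, carried melanoma. The mice were treated with diABZI, a small-molecule agonist of the innate immune sensor STING, or were controls. The 12 libraries form 4 groups of 3: LSK control, LSK STING agonist, GMP control and GMP STING agonist. LSK names a bone marrow fraction that lacks lineage markers and carries Sca-1 (encoded by Ly6a) and Kit, and GMP names granulocyte-monocyte progenitors. Group and replicate number came from each library's title and treatment label. The labels describe the material as single-cell samples and do not say how many cells or which mice a library came from, nor the dose or time of treatment. Nothing says that the 3 libraries of a group came from separate mice, so every p-value here measures the spread between these libraries, which may be technical.

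The authors deposited 1 table per cell type, with whole-number read counts per Ensembl gene for each library, per the file headers. The tables also hold the authors' base mean, a signal equal to the mean of the counts divided by median-of-ratios size factors (recomputed from the counts, 100% of genes within 0.1%), the authors' log2 fold change, and the authors' deposited p-value and adjusted p. Aligner, counter, strand setting and test tool are not given in the sources used here. The submitters' processing notes list the build mm9, whereas the positions in the deposited tables were the same as those of GRCm38 in GENCODE release M21 for 94.6% of the matched LSK gene identifiers and 94.7% of the matched GMP identifiers. Positions are therefore given as GRCm38. For LSK 29736 genes are listed and for GMP 31042, and 24982 identifiers are in both. Each table had 1 empty line, which was left out. Counts per library summed to between 30649314 and 47225983. Levels are counts per 1e6 counts (CPM). The reads carry no molecular identifiers, and count intervals and floors therefore cover counting error only.

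Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter, no fold threshold, and Benjamini-Hochberg adjustment at 0.05. LSK and GMP libraries were fitted separately for the effect of the agonist. The difference of the effect between cell types (an interaction term) and GMP against LSK in control mice came from a joint fit of all 12 libraries on the genes in both tables. The standard error (SE) of a log2 fold change was its size divided by the square root of the quasi-likelihood F. Group levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. The common biological coefficient of variation was 74.0% in LSK and 54.0% in GMP. In a group with 0 counts a fold was computed against a floor of 3 counts over the group's libraries, and with 1 to 3 counts the ratio is given with its 95% exact binomial interval.

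A set of 29 gene lists was tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01. The lists were tested again with an estimated correlation and with fry. Lists with fewer than 5 tested members were left out. The estimated setting could raise p even where the estimate lay below the preset. For the unfolded protein response list in GMP the estimate was 0.00514, and the camera p went from 1.10e-05 to 0.00994. A call lost with that setting therefore does not by itself show that the members were correlated. Samples, main tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, per cell type, the 12 called genes per direction with the largest change among those with at least 5 CPM in the higher group and no overlap between treated and control libraries. Where fewer than 10 genes were called in a direction, the rest up to 10 by smallest p are given as not passing. It also names up to 4 called members of each list and the genes of customary sort markers. The rule also took up to 2 further members by smallest p from lists with fewer than 2 called members; their values were computed, and most of them are left out of the text because they did not pass. Some items of that rule are not reported here. For the interaction it names the 10 genes with the smallest adjusted p, and between cell types 6 genes per direction. Predicted and clone-named genes were skipped. The lineage genes plotted, and Mpo, Elane, Prtn3, Ctsg, Car2, Klf1 and Gata1 between cell types, were chosen after their values were seen, as were the names given for the 18 genes called in both cell types. Where LSK and GMP levels are set side by side, they come from the scaling of all 12 libraries. Genes with close copies (Tgtp1 and Tgtp2, H2-Q6 and H2-Q7, the Oas1, Oasl, Phf11, Ifit and Xlr3 families, and the immunity-related GTPases) can share reads, as can overlapping and antisense genes, and their values are uncertain to that extent.

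Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with quality weights, no filter, a stricter filter of 5 CPM in 3 libraries, a log2 threshold of 1, a replicate block, the joint fit, and leaving out each library. Alternatives written for normalized values were not needed, since the tables hold counts. Likelihood-ratio tests, covariates from marker lists, and list tests on the interaction term were added after the data were seen. The gene tests of edgeR, DESeq2 and limma-voom were checked on simulated counts drawn from the real means and dispersions, with 50 genes changed at each of 4 sizes. Each gene had 1 mean over all libraries of the fit. The changed genes were drawn from those with a mean of at least 5 CPM, so the shares below do not cover lower genes. The limma-voom values are not reported here. At a true log2 change of 2, edgeR recovered 60% of 50 changed genes in LSK (13922 genes), 84% in GMP (15027 genes), 30% for the interaction and 60% between cell types (16857 genes each). At a log2 change of 1 the same shares were 20%, 30%, 4% and 10%. Among genes simulated without change, edgeR called 5 in LSK, 12 in GMP, 5 for the interaction and 7 between cell types, and DESeq2 called 73, 49, 89 and 109. Fry and the likelihood-ratio test were not checked in this way.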

Results

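Bone marrow cells labelled LSK and GMP, from melanoma-bearing mice, were profiled after treatment with the STING agonist diABZI and in controls. Each of the 4 groups had 3 libraries. Library totals were 32632893, 47225983 and 33463479 counts in LSK controls and 35243670, 34165301 and 39135896 in treated LSK. They were 35074217, 32005209 and 33833242 in GMP controls and 30649314, 36118138 and 38739074 in treated GMP. Genes with at least 1 count numbered 22280 and 24971 in STING agonist replicate 1 of LSK and of GMP, and between 15099 and 20870 in the other libraries. Correlations of log2 CPM between libraries of a group, across genes, were 0.863 to 0.910 in LSK controls, 0.863 to 0.883 in treated LSK, 0.889 to 0.898 in GMP controls and 0.939 to 0.943 in treated GMP. Some measures of the libraries separated treated from control fully. In LSK, mitochondrial genes held 1.70 to 2.41% of counts in controls and 2.72 to 3.61% in treated libraries, and the 10 most abundant genes 6.10 to 6.81% and 7.49 to 9.14%. In GMP, mitochondrial genes held 2.13 to 3.52% and 1.24 to 1.96%, and ribosomal RNA genes 0.853 to 2.59% and 0.418 to 0.675%. No correction was made for these measures, and their part in the differences below was not analysed here.

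The levels of genes customarily used to sort these cells bear on what the libraries hold. Kit, a receptor that LSK cells carry by definition, stood at 263 ± 73.3 CPM in LSK controls and 144 ± 24.8 CPM in GMP controls (SD, n = 3). Ly6a, which encodes Sca-1 and lies on chromosome 15 from 74994877 to 74998031, stood at 0.579 ± 0.176 CPM in LSK controls and 0.189 ± 0.303 CPM in GMP controls. Car2, a carbonic anhydrase abundant in erythroid progenitors, stood at 6719 ± 1585 CPM in LSK controls and 56.1 ± 4.37 CPM in GMP controls, and ranked between 2 and 4 from the top among the shared genes of the LSK control libraries. Mpo, the myeloperoxidase of primary granules, was the most abundant shared gene in every GMP library, at 19065 ± 165 CPM in controls, and ranged from 275 to 5508 CPM over the 6 LSK libraries. Cd34 and Fcgr3, customary markers of GMP, stood at 176 ± 87.0 and 13.03 ± 12.2 CPM in LSK controls and at 591 ± 54.6 and 310 ± 28.8 CPM in GMP controls, and Fcgr2b at 19.1 ± 13.2 and 170 ± 31.4 CPM. Because of these levels the LSK group is called LSK-labelled below, and its results are not taken to describe Sca-1-positive progenitors. Tmem173, the gene of STING, was measured at 2.56 ± 2.46 CPM in LSK-labelled controls and 19.1 ± 11.98 CPM in GMP controls.

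**Figure D1:**
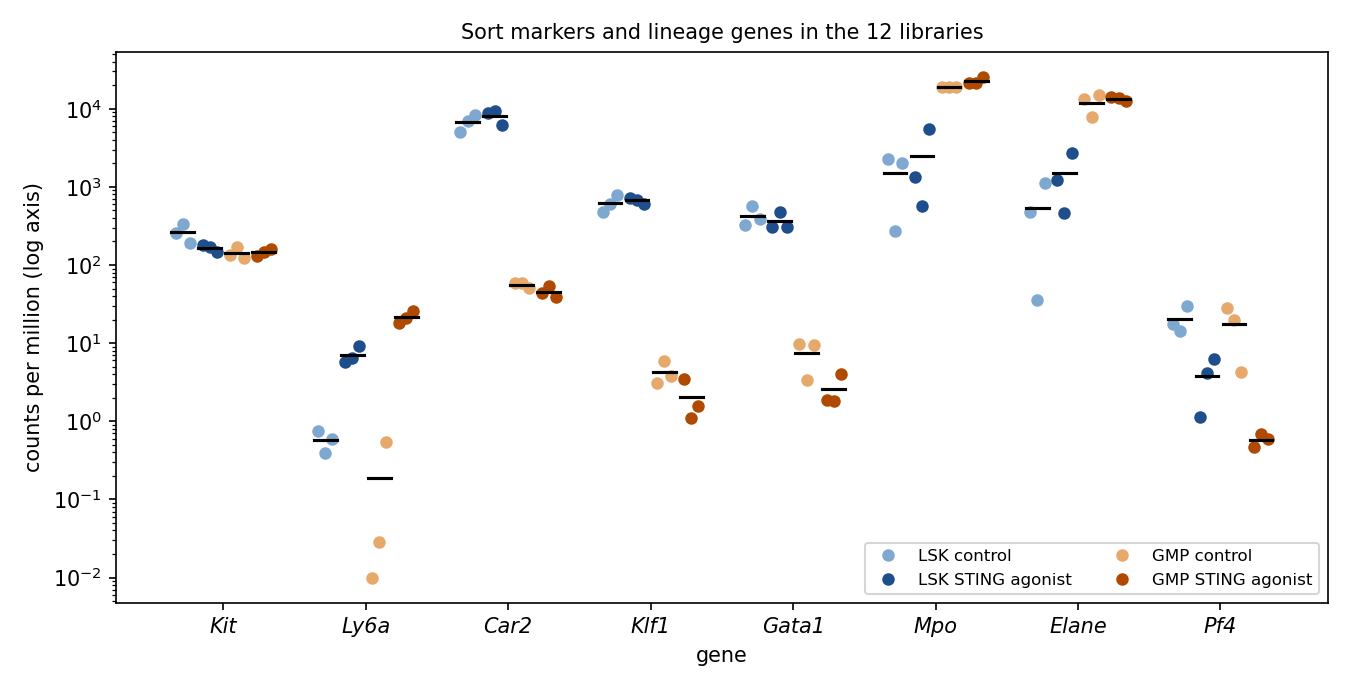
CPM (log axis) of 8 sort and lineage genes in each of the 12 libraries, 3 points per group with a black line at the mean; libraries with 0 counts are drawn at 0.01. Ly6a lies below 1 CPM in all 6 control libraries, whereas Car2 lies between 5055 and 9334 CPM in the LSK-labelled libraries.

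In LSK-labelled cells the agonist raised interferon-induced genes. Oas2, an antiviral oligoadenylate synthetase on chromosome 5, rose from 5.11 ± 0.869 to 184 ± 35.6 CPM, a log2 change of 5.17 ± 0.28 (SE, edgeR adjusted p = 0.000405, n = 3 per group). Igtp, an interferon-inducible GTPase, rose from 22.5 ± 3.24 to 377 ± 46.7 CPM (log2 change 4.07 ± 0.22). Irf7, the transcription factor that amplifies type I interferon and lies on chromosome 7 from 141262706 to 141266481, rose by 3.77 ± 0.33 on the log2 scale. Tnfaip3, a feedback inhibitor of NF-κB, rose from 32.3 ± 5.11 to 349 ± 56.7 CPM (log2 change 3.43 ± 0.23).

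Of 13922 genes tested, 47 were called, all 47 higher after the agonist and none lower, and treated and control libraries did not overlap at any of the 47. Non-overlap was found at 18.9% of all tested genes, where chance gives 10%. The authors' deposited values put 777 genes at an adjusted p below 0.05, among them all 47 with the same sign. The other largest rises were those of Tgtp1 (log2 change 4.70 ± 0.33), Tgtp2 (3.35 ± 0.30), Ddx60 (3.26 ± 0.49), Oasl2 (3.26 ± 0.36), Ifitm3 (3.18 ± 0.25), Usp18 (3.13 ± 0.35), Phf11c (3.11 ± 0.36) and Rtp4 (3.10 ± 0.35). Of 52 tested type I interferon-stimulated genes 14 were called higher (37 adjusted over the list alone), and the median log2 change was 1.87. Of 21 interferon-γ-induced GTPases and chemokines 7 were called higher (14 adjusted over the list alone), with a median of 3.30. Ifi47 reached 2.86 ± 0.27. Of 21 genes of MHC class I presentation 8 were called higher (18 adjusted over the list alone), with a median of 1.41. They included H2-K1 (1.45 ± 0.17), H2-Q6 (2.68 ± 0.20), H2-Q7 (2.43 ± 0.24) and the immunoproteasome gene Psmb10 (1.96 ± 0.22). These 3 lists kept their call with an estimated correlation, at adjusted p = 0.00261, 0.0224 and 0.0214.

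Outside these lists, the called genes of the fixed lists were Tnfaip3 and Nfkbia (2.42 ± 0.37) among 25 NF-κB and TNF response genes, and Samhd1 (1.72 ± 0.24) among 14 STING pathway components. Ddit3 (1.98 ± 0.28), the gene of a stress-induced transcription factor, was called among 24 unfolded protein response genes. The phosphatase gene Dusp1 (1.88 ± 0.27) was called among 25 immediate-early and heat-shock genes. Bst2 (2.07 ± 0.19), an interferon-induced gene also listed as a dendritic marker, was the called member of the dendritic list. No gene was called lower. The lower genes with the smallest p did not pass. Treml1, a platelet receptor gene, had 1247 counts in controls and 0 in treated libraries, at least 363-fold lower (adjusted p = 0.0528). Ankrd42 was at least 210-fold lower (adjusted p = 0.0844), and Sdc1 had 1216 against 3 counts, a ratio of 354 with an interval of 121 to 1718. Psap had a log2 difference of -1.77 ± 0.29, Cavin1 -2.07 ± 0.36, Zfp251 -2.35 ± 0.41, Angpt1 -2.33 ± 0.42, Got2 -1.02 ± 0.19, Ctr9 -1.13 ± 0.22 and Ccne1 -1.05 ± 0.21, with adjusted p from 0.0664 to 0.127. Among the customary sort markers, Ly6a had a log2 difference of 3.60 ± 0.81 (adjusted p = 0.202) and Kit of -0.67 ± 0.24 (adjusted p = 0.360), and neither passed. Beside these calls, the mean log2 CPM of the megakaryocyte and platelet list was 4.51, 4.74 and 4.36 in the controls and 1.98, 1.82 and 3.33 in the treated libraries. That of the granulocyte-monocyte progenitor list was 5.91, 2.75 and 5.84 against 5.58, 4.83 and 7.06.

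Camera with the preset correlation called 12 of 27 lists in LSK-labelled cells, 8 higher and 4 lower. Other splits of the same 6 libraries called up to 15 lists, so this count alone does not set treatment apart. The further 5 higher lists, with adjusted p for an estimated correlation, were immediate-early and heat-shock genes (median log2 change 1.01, adjusted p = 0.251), cytosolic ribosomal proteins (0.79, adjusted p = 0.251), granulocyte-monocyte progenitor genes (0.92, adjusted p = 0.580), p53 targets and apoptosis genes (0.47, adjusted p = 0.241) and oxidative phosphorylation genes (0.38, adjusted p = 0.575). The 4 lower lists were megakaryocyte and platelet genes (-1.49, adjusted p = 0.241), haematopoietic stem cell genes (-0.79, adjusted p = 0.251), DNA replication and G1/S genes (-0.31, adjusted p = 0.251) and glycolysis genes (-0.12, adjusted p = 0.515). No member of these 9 lists apart from Dusp1 was called among all genes. Adjusted over the list alone, 34 of 59 ribosomal protein genes were higher and 4 of 22 megakaryocyte genes lower. Of 25 immediate-early and heat-shock genes 10 were higher and 1 lower. The progenitor list lost its call with the preset correlation without control replicate 2 (adjusted p = 0.111) or STING agonist replicate 3 (0.0641). The p53 list lost it without control replicate 3 (0.0566) or STING agonist replicate 3 (0.0771), and the glycolysis list without STING agonist replicate 1 (0.0803).

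The count of called genes in LSK-labelled cells was 26, 27 and 24 without control replicate 1, 2 and 3, 11 without STING agonist replicate 1 and 19 without STING agonist replicate 2. It was 512 with DESeq2 (250 lower), 557 with no filter on low counts (285 lower), 78 with the stricter filter (6 lower), 107 in the joint fit (17 lower), 61 with limma-voom (3 lower) and 323 in an added likelihood-ratio test (126 lower). Without STING agonist replicate 3 it was 36 (4 lower). At an unadjusted p below 0.05 edgeR gave 810 higher and 832 lower genes, where chance gives 696 over both directions.

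**Figure D2:**
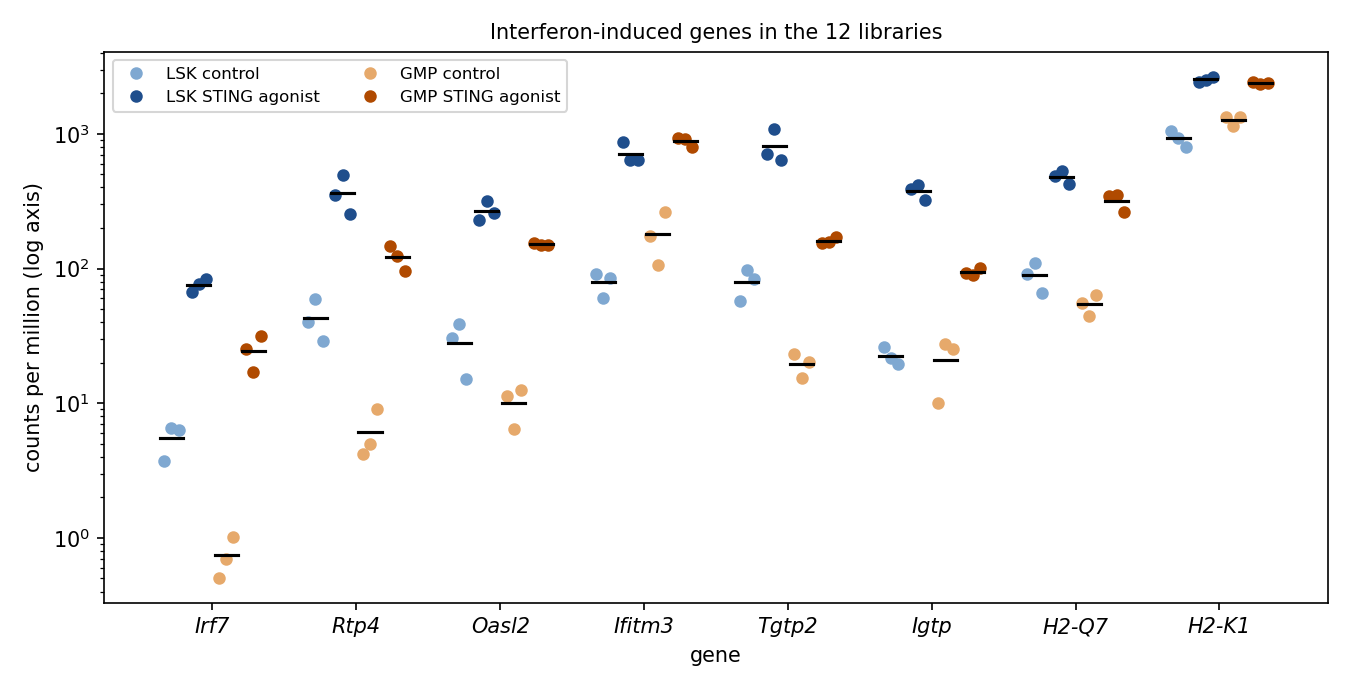
CPM (log axis) of 8 interferon-induced genes called in both cell types, 3 points per group with a black line at the mean. At each gene every treated library of a cell type lies above every control library of that cell type, for example 75.8 against 5.56 CPM on average for Irf7 in LSK-labelled cells.

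In GMP interferon-induced genes were also higher after the agonist, together with immediate-early genes. The median log2 change of the immediate-early and heat-shock list was 0.71 in GMP and 1.01 in LSK-labelled cells. That list was not called for a different effect between the cell types (camera with the preset correlation, adjusted p = 0.588). Ifit1, an interferon-induced gene that restricts viral translation, rose from 0.580 ± 0.459 to 34.6 ± 15.6 CPM, a log2 change of 5.89 ± 0.62 (SE, edgeR adjusted p = 0.00388, n = 3 per group). Hcar2, a metabolite receptor, rose from 7.62 ± 0.760 to 121 ± 10.5 CPM (3.98 ± 0.21). Ly6a rose from 0.199 ± 0.319 to 21.6 ± 4.08 CPM (6.75 ± 1.02, adjusted p = 0.0244). Ly6a encodes Sca-1, which LSK cells carry by definition. Whether treated and control fractions held the same mix of cells was not tested. Pf4, the platelet factor 4 gene on chromosome 5 from 90772435 to 90773383, fell from 17.7 ± 12.1 to 0.577 ± 0.0995 CPM (-4.93 ± 0.69, adjusted p = 0.0163).

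Of 15027 genes tested, 64 were called, 58 higher and 6 lower, with no overlap between treated and control libraries at any of them. Non-overlap was found at 17.1% of all tested genes, where chance gives 10%. The authors' deposited values called 456, among them all 64 with the same sign. The largest rises included Phf11d (log2 change 6.39 ± 0.82), Oasl1 (5.53 ± 0.95), the nuclear receptor gene Nr4a1 (5.13 ± 0.70), Irf7 (5.05 ± 0.44), Ifi44 (4.77 ± 0.36), the cytokine gene Il1b (4.76 ± 0.81), Rtp4 (4.33 ± 0.34) and Oas1g (4.25 ± 0.45). Xlr3b had 519 counts in treated libraries and 0 in controls, at least 173-fold higher. Of 53 type I interferon-stimulated genes 19 were called higher (43 adjusted over the list alone), with a median log2 change of 2.18. Of 18 interferon-γ-induced genes 5 were called higher (12 higher and 1 lower adjusted over the list alone), with a median of 1.82. They included Igtp (2.19 ± 0.35), Irgm2 (3.31 ± 0.53), Tgtp1 (3.66 ± 0.40) and Tgtp2 (3.04 ± 0.22). Of 21 MHC class I genes 4 were called higher (15 adjusted over the list alone), with a median of 0.92: H2-Q7 (2.55 ± 0.21), H2-Q6 (2.44 ± 0.20), H2-K1 (0.92 ± 0.14) and H2-T22 (1.38 ± 0.21). With an estimated correlation the adjusted p of these lists was 0.00295, 0.0129 and 0.0353.

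Of 23 immediate-early and heat-shock genes 6 were called higher (14 adjusted over the list alone, median 0.71, adjusted p = 0.0406 with an estimated correlation). Among them were Dusp1 (1.96 ± 0.20), Klf6 (1.52 ± 0.20), Nr4a1 and Fos (1.52 ± 0.21). Of these named genes, only Dusp1 was called in every fit without 1 library. The list kept its call in each of the 6 camera tests without 1 library, with the preset correlation. Of 28 NF-κB and TNF response genes 4 were called higher (5 adjusted over the list alone; median 0.30, adjusted p = 0.0564 with an estimated correlation). They were the chemokine genes Ccl2 (3.56 ± 0.36) and Ccl4 (2.20 ± 0.31), Il1b, and Zfp36 (1.01 ± 0.17), which encodes a protein that destabilises cytokine mRNA. Cd14 (2.35 ± 0.24) and Klf2 (2.06 ± 0.32) were called among 24 monocyte and macrophage genes (2 higher and 3 lower adjusted over the list alone; median -0.06). Ddit3 (1.83 ± 0.22) was called among 24 unfolded protein response genes (7 higher adjusted over the list alone) and Bst2 (1.62 ± 0.22) among 10 dendritic genes (1 higher and 1 lower adjusted over the list alone). Cd4 was called with 388 counts in treated libraries and 0 in controls, at least 129-fold higher. Beside Pf4, the falls named by the rule were those of Ighm, the immunoglobulin μ gene (-1.57 ± 0.26), and Amot (-1.51 ± 0.25). Mfsd2b (-3.04 ± 0.53), Rgs10 (-1.56 ± 0.28), Hist1h2ac (-1.79 ± 0.33), Rassf4 (-0.996 ± 0.19), Pld4 (-1.32 ± 0.25), Bcl2 (-1.16 ± 0.22) and Cenpf (-1.21 ± 0.23) did not pass, with adjusted p from 0.0507 to 0.0765. The mean log2 CPM of the megakaryocyte and platelet list was 3.17, 3.25 and 2.45 in the controls and 1.40, 0.849 and 1.58 in the treated libraries. That of the erythroid list was 2.33, 2.26 and 2.50 against 1.45, 1.46 and 1.71.

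Camera with the preset correlation called 17 of 28 lists in GMP, 12 higher and 5 lower. The further higher lists, with adjusted p for an estimated correlation, were cholesterol biosynthesis (median 0.50, adjusted p = 0.0564), unfolded protein response (0.28, adjusted p = 0.0557), glycolysis (0.40, adjusted p = 0.221), p53 targets and apoptosis (0.22, adjusted p = 0.146), DNA replication and G1/S (0.16, adjusted p = 0.422), oxidative phosphorylation (0.12, adjusted p = 0.559) and granulocyte-monocyte progenitor genes (0.18, adjusted p = 0.473). The lower lists were megakaryocyte and platelet (-1.35, adjusted p = 0.149), erythroid (-0.83, adjusted p = 0.152), eosinophil, basophil and mast cell (-1.10, adjusted p = 0.422), multipotent and lymphoid-primed progenitor (-0.18, adjusted p = 0.271) and progenitor cytokine receptor genes (-0.18, adjusted p = 0.578). With the preset correlation the G1/S call was lost without STING agonist replicate 3 (adjusted p = 0.102), the oxidative phosphorylation call without control replicate 2 (0.608). The multipotent progenitor call was lost without control replicate 3 (0.108), and the eosinophil call without control replicate 1 (0.1005) or STING agonist replicate 2 (0.0597). The granulocyte-monocyte progenitor call was lost without control replicate 2 (0.647), STING agonist replicate 1 (0.0912) or replicate 2 (0.112). The cytokine receptor call was lost without control replicate 1 (0.1005) or 2 (0.435) or STING agonist replicate 1 (0.0691) or 2 (0.0909).

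The count of called genes in GMP was 18 without STING agonist replicate 1, 18 without replicate 2 and 18 without replicate 3 of that group, with none lower in these 3 fits. Without control replicate 1 it was 45, with none lower. Pf4 then had an adjusted p of 0.141, 0.136, 0.178 and 0.0603, and 0.142 with limma-voom. In the same order of left-out libraries Ighm had 0.259, 0.337, 0.0904 and 0.0652, and Amot 0.281, 0.240, 0.253 and 0.132. Without control replicate 2 Ighm had 0.0781 and Amot 0.0854. Without control replicate 3 Ighm had 0.0946, and Amot kept its call at 0.0491. In the joint fit both had an adjusted p of 0.999. The count was 339 with DESeq2 (136 lower), 275 with no filter on low counts (116 lower), 40 in the joint fit (3 lower), 286 in an added likelihood-ratio test (98 lower) and 0 in an added fit with the mean of the megakaryocyte and erythroid lists as a covariate, which itself shared 92.4% of its variance with treatment.

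**Figure D3:**
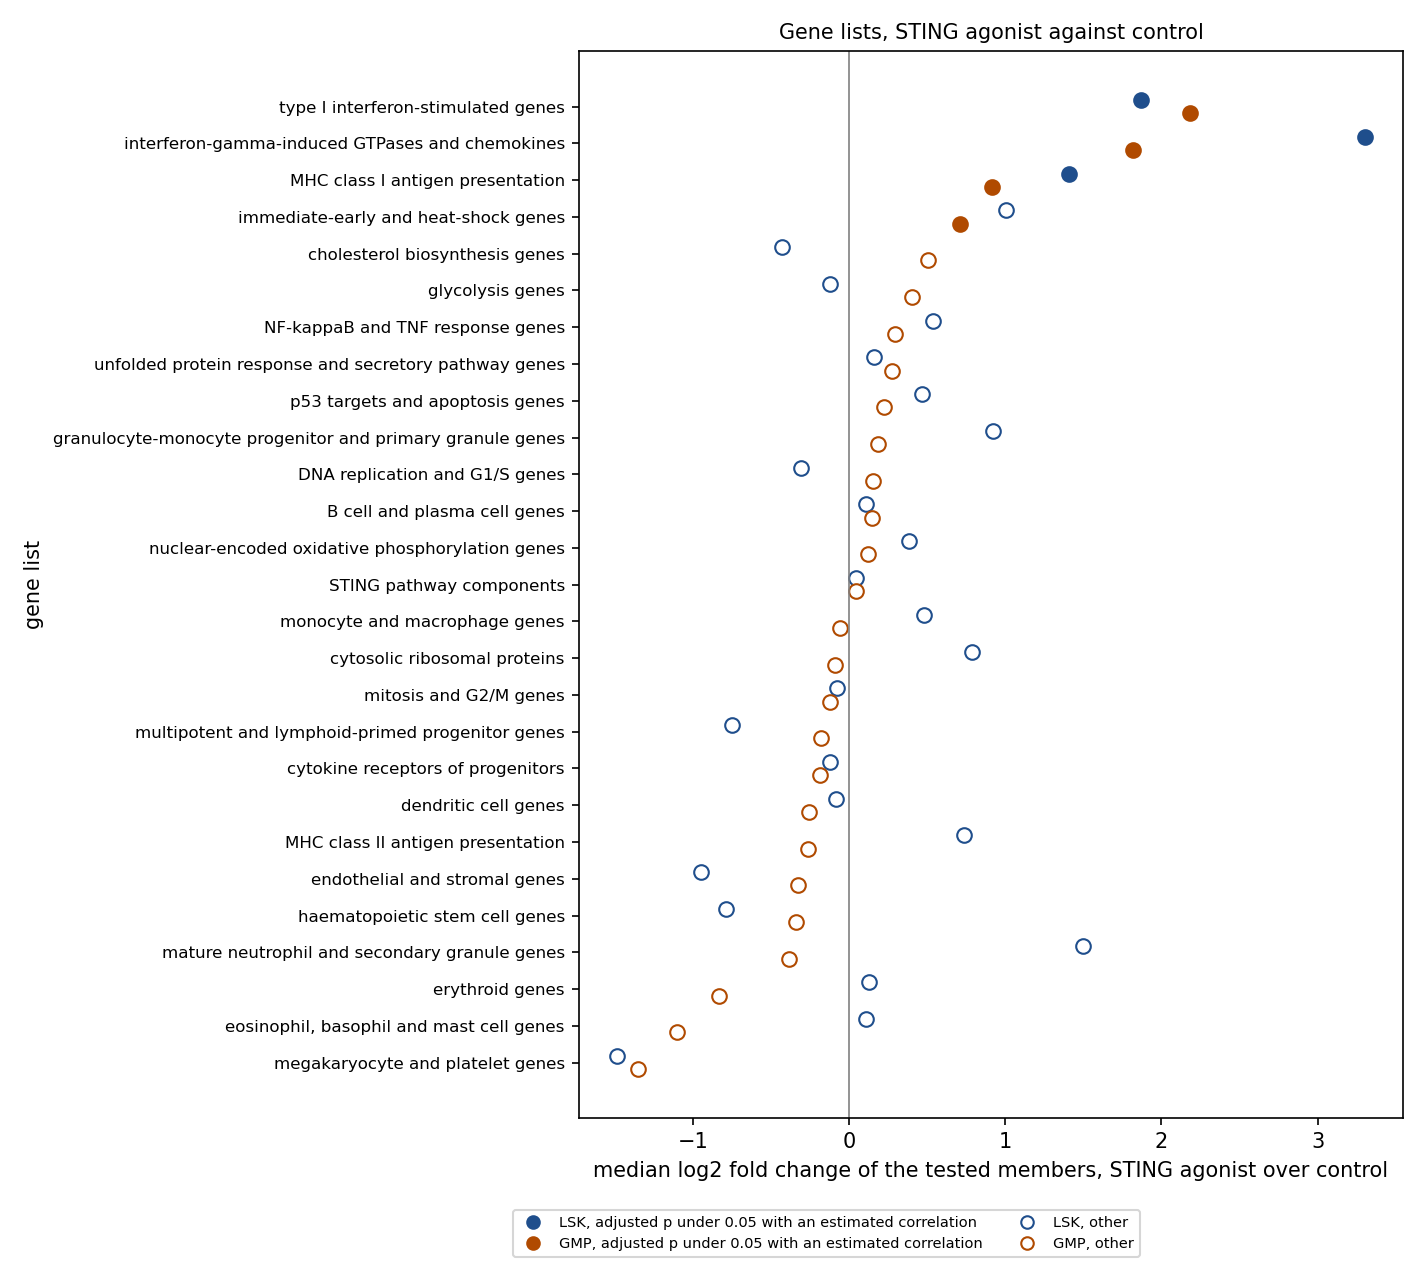
Median log2 fold change of the tested members of each gene list, STING agonist over control, in LSK-labelled (blue) and GMP (orange) libraries; filled points passed an adjusted p of 0.05 with an estimated correlation. The 3 interferon and MHC class I lists are filled in both cell types, and the immediate-early list in GMP.

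The effect of the agonist was compared between the cell types. Among 13159 genes tested in both, 18 were called higher in both against 0.196 for independent lists, and none lower in both. They were Tgtp1, Tgtp2, Igtp, Irgm2, Irf7, Oasl2, Ifitm3, Rtp4, Xaf1, Bst2, Ube2l6, Rnf213, H2-K1, H2-Q6, H2-Q7, H2-T22, Ddit3 and Dusp1. Of the 46 genes called in LSK-labelled cells and tested in both, 43 had the same sign in GMP, and of 62 called in GMP 58 had the same sign in LSK-labelled cells. Across all genes the log2 changes correlated weakly (Pearson r = 0.199, Spearman rho = 0.0619; genes are not independent replicates), 50.7% had the same sign, and r was 0.153 over the 13068 genes outside the 3 interferon and MHC class I lists. Without GMP control replicate 2 the Pearson correlation was 0.0985.

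**Figure D4:**
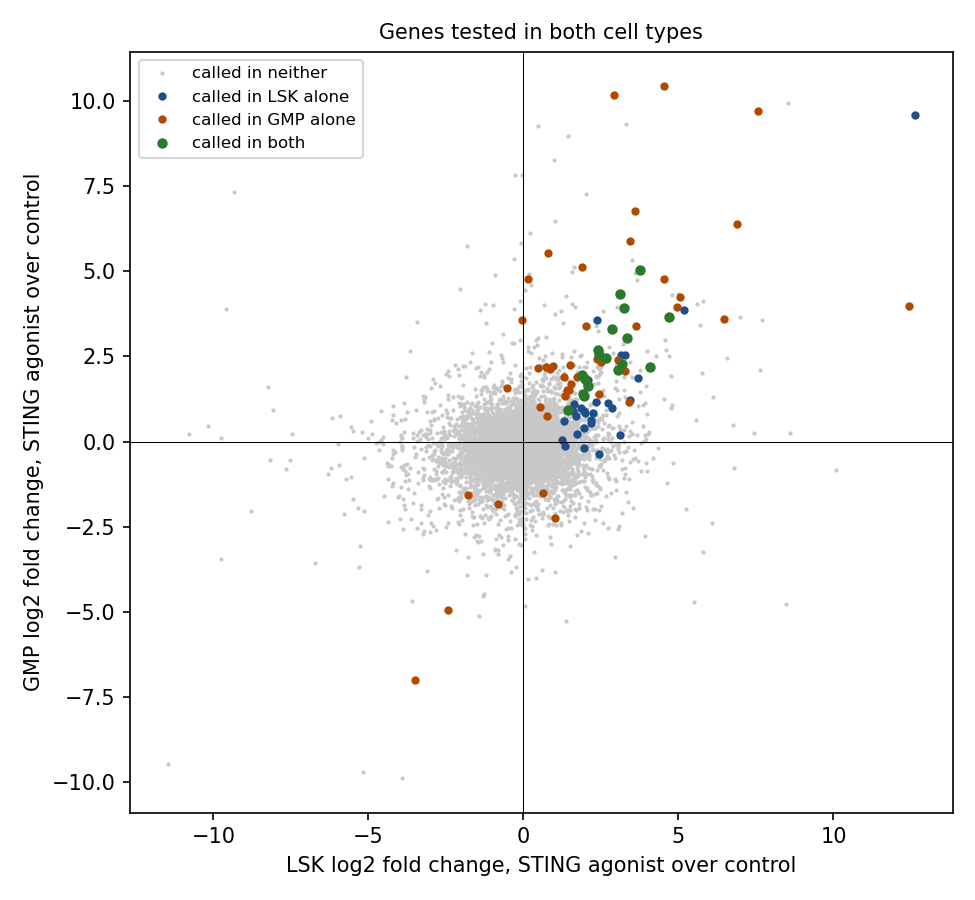
Log2 fold change of STING agonist over control in LSK-labelled (horizontal) and GMP (vertical) libraries for the 13159 genes tested in both, coloured by the cell type in which a gene was called. The 18 genes called in both lie at positive values on both axes.

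Of 16857 genes, none was called by edgeR for a difference of the effect between cell types, at a smallest adjusted p of 0.177, and 1707 had an unadjusted p below 0.05 (843 by chance). DESeq2 called 182 and limma-voom 2. In simulated counts 89 of 209 DESeq2 calls were of unchanged genes, a share that depends on how many genes were changed. Without 1 library edgeR called 22 (LSK STING agonist replicate 3), 2 (GMP control replicate 2) or 1 (LSK control replicate 3, GMP control replicate 3 or GMP STING agonist replicate 1). The genes with the smallest adjusted p, given as GMP minus LSK effect, were Tspo2 (-4.28 ± 0.67), Nfkbia (-2.75 ± 0.43), Gadd45g (-2.11 ± 0.33) and Ccne1 (2.20 ± 0.36). Others were Ifi47 (-1.83 ± 0.33), Lgals9 (-1.59 ± 0.29) and Gnpat (1.36 ± 0.26, adjusted p = 0.241), and 3 genes with at most 2 counts in GMP controls, for which no fold is given. These were Igsf3 (127 counts in treated GMP against 2), Igf2r (92 against 1) and Col5a1 (0 in GMP controls). The log2 change of Nfkbia, the NF-κB inhibitor gene, was 2.42 in LSK-labelled cells and -0.37 in GMP, and that of the cyclin gene Ccne1 was -1.05 and 1.10. Neither passed the test of the difference.

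GMP and LSK-labelled libraries of control mice were compared to give the baseline. Of 29 granulocyte-monocyte progenitor and primary granule genes 25 were called higher in GMP (median log2 difference 3.65), among them Mpo (3.65 ± 0.81), Elane (4.48 ± 0.95), Prtn3 (4.24 ± 0.78) and Ctsg (4.11 ± 0.87). Of 22 erythroid genes 15 were called lower in GMP and 1 higher (median -5.59), among them Car2 (-6.90 ± 0.28), Klf1 (-7.18 ± 0.45), the master regulator of erythroid genes, and Gata1 (-5.83 ± 0.49). Across 16857 tested genes, all listed for both cell types, 1943 were called, 767 higher and 1176 lower in GMP. Genes listed for 1 cell type alone were not compared. The largest differences were, higher in GMP, Prss34 (at least 7846-fold), Prg2 (at least 1067-fold), Arhgef10l (at least 293-fold), Hcar2 (at least 291-fold), Bmx (at least 216-fold) and Matn2 (ratio 695, interval 192 to 5746). Prss34 and Prg2 are genes of basophil and eosinophil granules, and both had wide spread between GMP controls, at 201 ± 237 and 27.0 ± 30.3 CPM. Higher in LSK-labelled cells were Slc38a5 (at least 4227-fold), Prss50 (at least 2989-fold), Sh2d4a (at least 2779-fold), Col5a1 (at least 2547-fold), Aldh1a7 (at least 1694-fold) and Sphk1 (26158 against 1 count, ratio 23518, interval 4221 to 928963).

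Further lists in this comparison were higher in GMP for unfolded protein response genes (17 of 25 called higher and 3 lower) and lower for mitosis genes (14 of 36 called lower) and DNA replication genes (7 of 37 called lower). Camera called 16 of 28 lists with the preset correlation, and 1, the erythroid list, kept its call with an estimated correlation (adjusted p = 0.0276), whereas fry called 18. For the granulocyte-monocyte progenitor, unfolded protein response, mitosis and DNA replication lists that adjusted p was 0.122, 0.122, 0.128 and 0.122. The gene count was 1019 without LSK control replicate 2, 1078 without GMP control replicate 1, 1187 without GMP control replicate 3 and 3052 with DESeq2. In simulated counts DESeq2 called 109 unchanged genes. Far fewer genes were changed there than were called here, so no share of false calls follows for the 3052.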

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

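The list tests of the difference between cell types, and the test of treatment as the origin of the myeloid genes, were chosen only after the results were seen. Camera with the preset correlation of 0.01 called 10 of 28 gene lists for a different effect of the agonist in GMP and LSK-labelled cells, and none of the 10 was called with an estimated correlation. Fry called 1, the cholesterol biosynthesis list (adjusted p = 0.00556), of which 8 of 24 members had a higher effect in GMP when adjusted over the list alone. Values are median log2 differences, GMP effect minus LSK effect. In GMP the effect was lower for interferon-γ-induced genes (-1.005, adjusted p = 0.000149, and 0.226 with an estimated correlation), MHC class I genes (-0.45, 0.000435 and 0.226) and cytosolic ribosomal proteins (-0.87, 7.90e-12 and 0.522). It was also lower for granulocyte-monocyte progenitor genes (-0.71, 3.58e-05 and 0.569), mature neutrophil genes (-2.91, 0.0110 and 0.645) and erythroid genes (-1.25, 0.0105 and 0.412). It was higher for haematopoietic stem cell genes (0.88, 0.0159 and 0.383), G1/S genes (0.31, 1.94e-05 and 0.226), glycolysis genes (0.78, 6.79e-06 and 0.226) and cholesterol biosynthesis genes (0.93, 3.55e-06 and 0.0826). Of 100 relabellings of treatment within the cell types, 40 called at least as many lists as the real one (10), and the highest of the others called 16, so chance cannot be excluded for this count. Relabellings that keep the real split in 1 cell type carry the effect of the agonist into the difference. Each of these called at least 10 lists, so the 40 are not a clean measure of chance. For single genes the real count was 0, which all 100 relabellings reach, so this comparison says nothing about chance. Of the 100, 79 called 0. The highest, 138, came from the relabelling that turned treatment around in GMP alone, which tests the effect that the cell types share. The 9 relabellings that set LSK control replicates 1 and 3 and STING agonist replicate 3 against the other LSK libraries called 17 to 31, whereas within LSK alone that split called 0 genes and 15 lists.

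The granulocyte-monocyte progenitor and neutrophil lists were present at uneven levels in the LSK-labelled libraries. The mean log2 CPM of the neutrophil list was 0.446, -2.08 and 0.696 in the controls and 0.313, -1.19 and 3.94 in the treated libraries. Only STING agonist replicate 3 lay above every control. The mean of the first list was 2.75 in control replicate 2, 5.91 and 5.84 in the other controls, and 5.58, 4.83 and 7.06 in the treated libraries. For the first list treatment as the whole origin is argued against, since its highest control lay above its lowest treated library by 1.09 on that scale. Reads spreading from GMP libraries would leave 471 GMP-high genes at 1 fraction of their GMP level. The interquartile range of the log2 fraction ran from 0.952 to 2.03 over the 6 libraries, which by itself decides nothing. In the LSK-labelled controls Prss34, Prg2, Arhgef10l, Hcar2 and Bmx had 0 counts, against 21162, 2877, 789, 785 and 582 in GMP controls. Matn2 had 2 against 1250. These genes were named for their large difference. Spread at 1 fraction as the whole origin is argued against for the control libraries, and stays open for the treated ones. A differing share of myeloid progenitors in the sorted fraction was not tested and may remain among the explanations.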

How the results depend on the processing

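The likelihood-ratio and covariate fits and the renumbering of replicates were chosen only after the results were seen. Upper-quartile and RLE factors kept the 4 counts of called genes, and RLE factors the 2 counts of called lists, within 1.5 times. The cause of changes below was not tested unless stated. LSK genes (47) became 512 with DESeq2, 557 with no filter, 78 with the stricter filter (fewer genes tested), 10 with the replicate block, 107 in the joint fit, 323 with the likelihood-ratio test, and 11 to 36 without 1 library. GMP genes (64) became 339 with DESeq2, 275 with no filter, 20 with the block (none lower), 40 in the joint fit, 286 with the likelihood-ratio test, 0 with the megakaryocyte and erythroid covariate, and 18 to 78 without 1 library. With that covariate, which shared 92.4% of its variance with treatment, the interferon list median went from 2.18 to 1.59 and its median SE from 0.423 to 1.34. Interaction genes (0) became 182 with DESeq2, 2 with limma-voom and 0 to 22 without 1 library. GMP against LSK (1943) became 3052 with DESeq2 and 1019 to 2032 without 1 library. LSK lists (12) became 3 with an estimated correlation, 3 with fry and 10 to 16 without 1 library. GMP lists (17) became 4, 8 and 14 to 17 in the same order. The correlation of effects (0.199) was 0.283 with the stricter filter, 0.161 with the block and 0.0985 to 0.204 without 1 library. The labels do not say that replicate numbers pair the samples. Treated LSK and GMP libraries of the same number had deviations correlated at 0.0828 to 0.167, and those of other numbers at -0.104 to 0.0158. Elsewhere not every sample correlated best with its own number: LSK control 1 correlated with STING agonist 1 at 0.0643 and with STING agonist 3 at 0.136. Of 216 numberings of the libraries within groups, 3 gave a sum of same-number correlations as high as the real one, the real one included. This is a hint from the data that numbers mark something shared, and the design does not say what.

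No result that changed sign was called at first. In LSK, Ms4a2 (-1.92) was 0.27 with limma-voom and -2.61 to 0.032 without 1 library. Cd72 was -2.73 to 0.42; Fcgr3 -0.028 with the myeloid covariate and -0.60 to 2.23 without 1 library. Tmem173 was -0.0101 with RLE and with DESeq2, -0.92 with limma-voom, -0.66 with the block, -1.39 with the covariate and -1.34 to 1.12 without 1 library. In GMP with the covariate, H2-Aa was 0.17, Irf8 0.14, Csf1r 1.24, Thy1 -0.30, Pecam1 0.61, Ednrb -2.21, Rpl27 -0.43, Cox5b -0.038, Kit 0.52 and Cd34 0.11. Without 1 GMP library H2-Aa ran from -1.58 to 0.15, Kit from -0.092 to 0.15 (0.034 in the joint fit), Fcgr3 from -0.038 to 0.12 (-0.00964 with the stricter filter) and Tmem173 from -0.58 to 0.84. The ribosomal list in GMP had an adjusted p of 3.42e-15 to 0.659 without 1 library, and turned lower at 0.000471 without GMP control replicate 2. Of the genes called, 11 of 47 in LSK, 15 of 64 in GMP and 826 of 1943 between cell types were called in every fit without 1 library, and all kept their sign. Over all named genes and lists, the alternatives left 2749 gene values and 542 list values on the same side, moved 241 and 30 past the threshold and 248 and 59 off it, and turned 34 and 1 in sign. At a true log2 change of 1, 20% of simulated changed genes were found in LSK and 30% in GMP, which limits what a missing call says.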

Other observations

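The tests of a label swap, of red cells, of the sort gate and of Ly6a reads lost to paralogs were chosen only after the results were seen. In LSK-labelled cells Flt3, a cytokine receptor gene of early progenitors, had a log2 difference of -3.05 ± 0.99 (SE, adjusted p = 0.337, n = 3 per group) and did not pass. Atf3, a stress-induced transcription factor gene, stood at 1.25 ± 1.59 CPM in controls and 118 ± 36.8 CPM in treated libraries (SD, n = 3; adjusted p = 0.0528). In GMP, Pmaip1, a pro-apoptotic p53 target, stood at 10.5 ± 7.50 and 107 ± 26.4 CPM (adjusted p = 0.0738). Cavin2 was at least 118-fold lower (adjusted p = 0.0567), and Irf8 and Csf1r, genes of the monocytic lineage, differed by -1.06 ± 0.26 and -1.35 ± 0.36 (adjusted p = 0.198 and 0.231).

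Lists that camera did not call in LSK-labelled cells, with median log2 differences, were MHC class II (0.74), NF-κB and TNF response (0.54), STING pathway (0.04), and multipotent progenitor genes (-0.75). The others were mature neutrophil (1.496), monocyte (0.48), dendritic (-0.08), eosinophil, basophil and mast cell (0.11), erythroid (0.13), B cell (0.11), endothelial and stromal (-0.94), mitosis (-0.08), unfolded protein response (0.16), cholesterol biosynthesis (-0.43) and cytokine receptor genes (-0.12). In GMP they were MHC class II (-0.26), STING pathway (0.04), haematopoietic stem cell (-0.34), mature neutrophil (-0.38), monocyte (-0.06), dendritic (-0.25), B cell (0.15), T and NK cell (0.23), endothelial and stromal (-0.32), mitosis (-0.12) and ribosomal protein genes (-0.09). The melanocyte list had 3 and 4 tested members and the T and NK cell list 4 in LSK-labelled cells, too few to test. Median and test differed in sign for the eosinophil and B cell lists in LSK-labelled cells (mean -0.09 and -1.26, test lower) and for the STING pathway (mean -0.01, test lower) and ribosomal lists (mean -0.06, test higher) in GMP. The monocyte list in GMP had a mean of 0.10 against a lower median and test.

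Between the cell types in controls, camera also called the mature neutrophil (median 4.18), monocyte (2.93), eosinophil, basophil and mast cell (2.76), cytokine receptor (1.34), multipotent progenitor (1.16), MHC class II (1.40) and dendritic lists (0.98) higher in GMP. It called the haematopoietic stem cell (-0.95), megakaryocyte (-0.99), type I interferon (-0.64) and cholesterol lists (-0.45) lower in GMP, and with an estimated correlation none of these 11 was called, at adjusted p from 0.122 to 0.380.

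The LSK-labelled controls held erythroid genes at high levels, with Klf1 at 619 ± 151 CPM and Gata1 at 426 ± 124 CPM. A swap of the LSK and GMP labels is argued against, since Mpo, Elane, Prtn3 and Ctsg were higher in GMP controls by a median of 4.18 on the log2 scale, with no overlap for 4 of 4. Mature red cells are argued against, since the summed globin count (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt) was at most 0.281% of the Car2 count. Loss of reads shared between these globin genes was not tested. A sort gate that held Kit-positive Sca-1-negative progenitors stays open. The values that go with it are 15 erythroid list members called higher than in GMP, Kit of at least 193 CPM and Ly6a of at most 0.746 CPM, but they are the values that raised the question and do not test it. Single-cell or small-pool sampling was not tested, and the gate used is not given in the sources used here.

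Ly6a, the gene of Sca-1, was below 1 CPM in all 6 control libraries and at 7.08 ± 1.80 CPM in treated LSK-labelled and 21.8 ± 4.07 CPM in treated GMP libraries. Loss of reads to an overlapping gene is argued against, since 0% of its exon bases were covered by another gene. Loss to paralogs as the whole cause is argued against. Of the 50-base words of its transcripts 19% also occur in Ly6c1, Ly6c2, Ly6i or I830127L07Rik, and in each of 4 equal parts of each transcript at least 51.7% occur in no other gene. If every read came from the part with that lowest share, the highest LSK-labelled control would stand at 1.44 CPM.

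Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For LSK genes the real split called 47 and the highest of the others 0 (1 of 10 splits as large), and for LSK lists 12 and 15 (3 of 10). For GMP genes they were 64 and 0 (1 of 10), and for GMP lists 17 and 11 (1 of 10). In a fit of the 6 control libraries GMP against LSK called 1352 genes and at most 0 in the other splits (1 of 10), and 14 and 13 lists (1 of 10). Among 100 combinations of splits, 4 had an absolute Pearson correlation between the effects in the cell types as large as the real 0.199, the real one included, with a highest of 0.223. The combinations take LSK and GMP libraries as independent. Treated libraries of the same number had deviations correlated at 0.0828 to 0.167, and the replicate block lowered the real correlation to 0.161. No conclusion on chance is therefore drawn from this share.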
